A study of Mus musculus with 55 samples.

How the data were processed

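The measurements were chromatin immunoprecipitation sequencing (ChIP-seq) of bone marrow-derived macrophages (BMDM) from mice. Acetylation of histone H3 at lysine 27 (H3K27ac) marks active promoters and enhancers, and p300 is an acetyltransferase that places this mark. Per the labels' protocols, cells were treated with 3'-sialyllactose (3'SL, a sialylated milk oligosaccharide) at 100 µg/ml, with lipopolysaccharide (LPS, the bacterial ligand of TLR4) at 10 ng/ml, with both, or with the vehicle PBS, for 2 h or 6 h. Separate cells were treated with the LXR agonist GW3965 at 1 µM for 18 h for ChIP-seq of LXR, SREBP and p300. ATAC-seq, which maps open chromatin, and p65 ChIP-seq came from another study of untreated and Kdo2-lipid A (KLA) treated macrophages. The labels list 55 samples in 35 groups, and groups were taken from those labels alone. The treatment label reads 1 h in the replicate 1 H3K27ac libraries of LPS, 3'SL and both titled 2 h, and vehicle PBS in the 2 h replicate 2 library of both. The titles were followed.

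Per the submitters' processing notes, Bowtie2, HOMER, DESeq2 and the build mm10 were used; their versions are not given in the sources used here. Per the file headers, the deposited H3K27ac and p300 tables hold signal made with HOMER annotatePeaks.pl on mm10, that is, tags in a 1000 bp (H3K27ac) or 200 bp (p300) window around each region, scaled by the authors to 10000000 tags per library. The regions were 97113 merged ATAC peaks, 80096 merged transcription factor peaks or 87466 merged H3K27ac peaks. The ATAC peaks were those reproducible between replicates in the other study, merged by the authors, per the labels. The deposited ATAC list carries a score per peak whose definition is not given in the sources used here; it was used only to rank peaks within that list. The LXR, SREBP, p300 and p65 lists hold positions alone, so the planned choice of the 5 best scored peaks per list could not be applied. Peaks of p65 were called by the authors with HOMER findPeaks against input and merged over time points, per the labels. The parameters used for the other lists are not given in the sources used here. Each factor has 1 list, so replicates cannot be compared at the level of peaks.

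Each signal value times its library's total, which is in the file headers, divided by 10000000 came out within 0.05 of a whole number for 100% of the regions in each library. Tags were thus recovered and used for filtering, for counting errors and for the count tests. Tables have 13 columns of per-sample values that match no sample's labels and were not used. After that, 15 H3K27ac and 14 p300 libraries entered the models. Vehicle had 1 library, of replicate 2, for H3K27ac at 6 h and for p300 at both times, so these comparisons assume that the lone library varies like the other groups. The labels list a replicate 1 vehicle sample for each of these 3 groups too, but no column was matched to them and they were not used here. Every other group had 2. The deposited values of replicates differed by more than counting noise in every group (chi-square per degree of freedom 8.34 to 28.3 over regions of at least 20 tags), so none was counted as a duplicate. Nothing in the labels says whether replicates were separate animals or cultures; p-values then measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

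Regions were filtered with edgeR's filterByExpr on recovered tags, which left 77387 H3K27ac and 62225 p300 regions of the ATAC table. Values were rescaled by the tags in these regions times TMM factors and put back on the mean scale of the authors' values, since the share of tags in regions differed between replicates. They were tested as log2(value + 1) with limma's trended empirical Bayes test in a group-means model over all groups of a mark (7 and 6 residual degrees of freedom). Fold changes are on the log2(value + 1) scale, which understates changes of low regions. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no fold threshold. Values printed for regions and genes are these rescaled tags per 10000000 mapped tags, called normalised tags, as mean ± SD. Against groups with 0 tags a bound is given from the pooled tags of the treated libraries, with a floor of 3 tags over the group, so it can differ from the ratio of printed means. With 1 to 3 tags, the ratio of values is given with the exact 95% interval for a ratio of counts.

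The test departs from the written plan. The plan named edgeR's quasi-likelihood test on tags, and limma only for values from which whole reads could not be recovered. Whole reads were recovered, but limma was used because the deposited values are normalized, and edgeR became an alternative chosen after the data were seen. Calls from edgeR with and without the replicate as a block, and from limma on the authors' scaling, had been looked at before the choice was settled. Limma with TMM factors gives more calls against vehicle for p300 than edgeR without the block, DESeq2 or the authors' scaling, so those counts stand beside it. For 3'SL with LPS against LPS alone, no fit of either mark called a region. The plan also assumed 16 libraries per mark.

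Gene-level values are sums over the ATAC regions whose nearest transcription start site in the authors' annotation is that gene, within 100 kb (16710 genes for H3K27ac and 15971 for p300). The 14 gene lists were fixed before the data were examined, as were the groups, alternatives other than those named above as later, and the rule for named genes. They cover NF-kB inflammatory genes (35 genes), interferon response (32), TLR4 signalling (20), anti-inflammatory and resolution genes (20), LXR targets (18), cholesterol synthesis under SREBP2 (26), fatty acid synthesis under SREBP1 (19), Siglecs and sialic acid metabolism (17), macrophage identity (20), housekeeping (15), and markers of neutrophils (12), lymphoid cells (15), dendritic cells (11) and stromal or erythroid cells (12). Scd1, Scd2 and Srebf1 are on both the LXR and the fatty acid list, and Siglech is on both the Siglec and the dendritic list. Macrophages themselves express some of the dendritic and neutrophil markers. Lists and region classes were tested with camera, which compares a set with all other genes or regions, at a preset correlation of 0.01 and again with the correlation estimated. Adjustment was over lists within a comparison. Set medians are relative to the median of all tested genes or regions.

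Classes of LPS-induced and LPS-repressed regions were taken from the other mark at the same time (adjusted p under 0.05 and a log2 change of at least 1, or the 500 regions of smallest p where under 50 passed), so that the class and the comparison share no libraries. Bound classes were ATAC regions overlapping an LXR, SREBP or p300 peak by at least 1 bp, and regions overlapping none of these. The p65 class was not run, because the p65 list holds coordinates past the ends of mm10 chromosomes. Consensus sites (NF-kB GGGRNWYYCC, ISRE GAAANNGAAA, AP-1 TGASTCA, PU.1 GAGGAAGT, DR4 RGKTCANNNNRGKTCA, SRE TCACNCCAC, C/EBP TTGCNNCAA) were searched in mm10 sequence on both strands. Shares in called regions were compared with 5 tested but uncalled regions per called region, matched in 10 GC bins, by a two-sided Fisher's exact test.

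Named regions are, per direction, up to 8 of the largest change past the threshold with both treated libraries beyond all controls, at most 1 per nearest gene (3 for 3'SL against PBS). Where none passed, the 3 of smallest p were taken. Up to 3 list members of smallest p past the threshold were named per list, or the 1 of smallest p as a value, and Il1b, Tnf, Il6, Nos2, Cxcl10, Abca1, Abcg1 and Scd2 were always given. Further genes of the written rule are not reported here. Not all regions and members taken by this rule are printed.

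Replicate numbers in the labels were checked for pairing. The difference of replicate 1 from replicate 2 correlated across regions between groups in all 21 pairs of groups for H3K27ac (r = 0.45 to 0.67) and all 15 for p300 (0.19 to 0.38), so same-numbered libraries deviate together. Unless another setting is named, calls are by limma without the block, with TMM factors, the filter, ATAC regions and the 100 kb window, and values with the block stand beside a result where they change it. Alternatives were RLE size factors, library totals over the regions used, no filter, pseudocounts of 0.5 and 5, DESeq2, pooled vehicles, other region tables, a 10 kb gene window, classes from the same mark, stricter peak overlap, and leaving out each library. Limma without the block was tested on data simulated from these libraries, with 200 regions (20 expected tags or more) changed by known folds.

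Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and the package data.table (1.17.8); bedtools 2.31.1; and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. H3K27ac libraries held 4.20 to 39.6 M tags and p300 libraries 3.20 to 18.1 M tags. In the shallowest, p300 vehicle at 2 h, 1 tag was worth 3.13 of the deposited units, so low p300 regions are imprecise there.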

Results

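To ask how the sialylated milk sugar 3'SL acts on the chromatin of macrophages at rest and under LPS, H3K27ac and p300 were profiled in BMDM given PBS, 3'SL, LPS or 3'SL with LPS for 2 h or 6 h. For H3K27ac, replicate 2 libraries held 8.67 M tags with PBS at 2 h, 10.6 M with PBS at 6 h, 19.3 M with 3'SL at 2 h and 4.20 M with 3'SL at 6 h. With LPS they held 13.2 M at 2 h and 7.42 M at 6 h, and with 3'SL and LPS 22.5 M at 2 h and 39.6 M at 6 h. Replicate 1 libraries held 12.1 M with PBS at 2 h, 11.4 M and 16.8 M with 3'SL at 2 h and 6 h, 16.8 M and 15.5 M with LPS, and 16.4 M and 15.9 M with both. For p300, replicate 2 libraries held 3.20 M and 7.11 M with PBS at 2 h and 6 h, 4.15 M and 8.75 M with 3'SL, 5.11 M and 6.38 M with LPS, and 5.40 M and 3.84 M with both. Replicate 1 libraries of p300 held 16 M and 16.7 M with 3'SL, 15.0 M and 13.6 M with LPS, and 18.1 M and 14.9 M with both. Each treated group had n = 2. Vehicle had n = 2 for H3K27ac at 2 h and n = 1 elsewhere, so differences from a lone vehicle lack a control replicate. Tags in 1000 bp windows around the 97113 ATAC regions (ATAC windows, which can overlap) came to 53.9% to 79.3% of these H3K27ac libraries. In inputs, without immunoprecipitation, this share was 8.65% to 8.85%. For p300 (200 bp windows) it was 20.1% to 27.5% in replicate 2 but 6.12% to 9.42% in replicate 1, against 4.77% in its input.

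**Figure D1:**
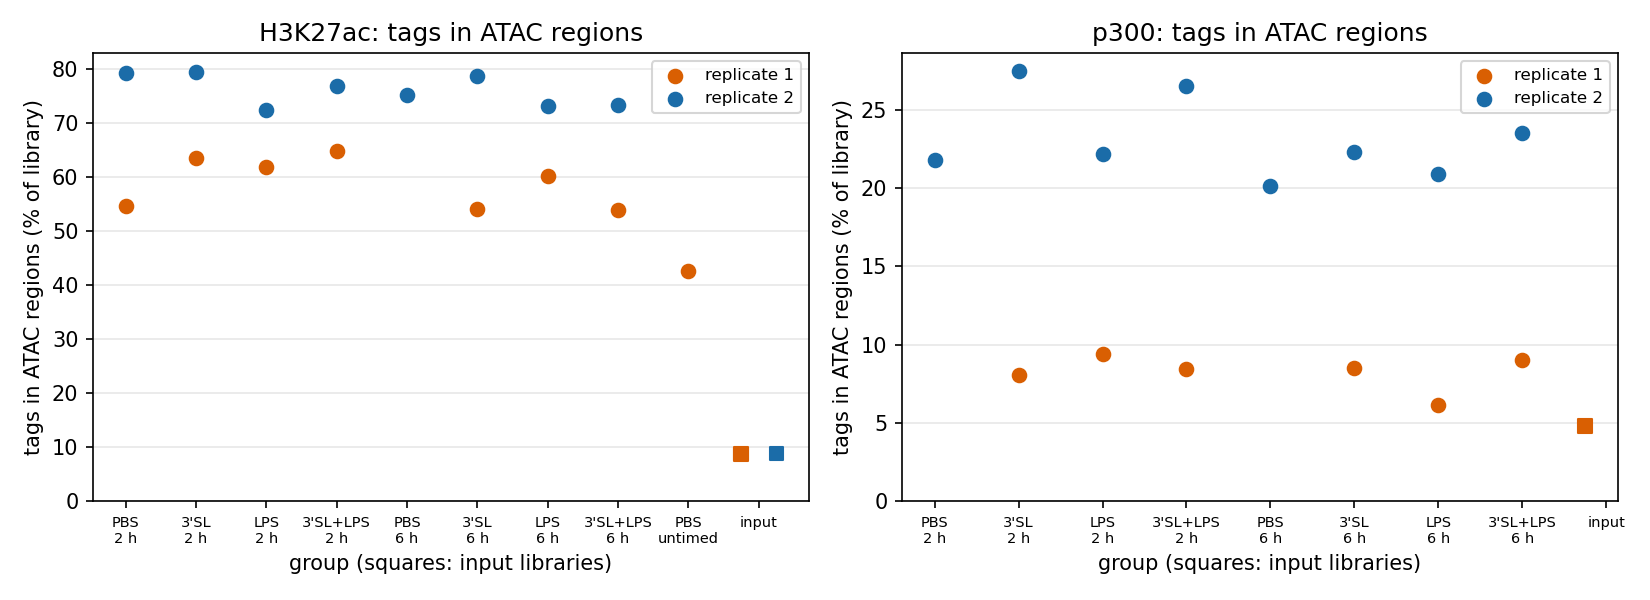
Tags in the ATAC windows as % of each library (y axis) by group (x axis). Replicate 1 is orange, replicate 2 blue and inputs are squares. Every p300 library of replicate 1 lies at or below 9.42%, close to its input at 4.77%, and every p300 library of replicate 2 at or above 20.1%.

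LPS for 2 h raised H3K27ac around genes of inflammation and interferon signalling. Socs3, a feedback inhibitor of cytokine receptors, rose from 472.0 ± 43.1 to 2936 ± 469.8 normalised tags (SD, n = 2 each; log2 change 2.63, SE 0.28, adjusted p = 0.0015). Nfkbie, an inhibitor of NF-kB, rose from 125 ± 5.05 to 776 ± 82.8 (2.62, SE 0.28, adjusted p = 0.00159). Il1b, which encodes the cytokine IL-1β, rose from 314 ± 38.9 to 1904 ± 108 (2.60, SE 0.33, adjusted p = 0.00272). Edn1, the gene of endothelin, rose by 1.72 (SE 0.20, adjusted p = 0.00232), and the costimulatory receptor gene Cd40 by 3.36 (adjusted p = 0.00273). Larger changes with a wider spread were seen for the chemokine genes Ccl5 (148 ± 73.5 to 2599 ± 839; log2 change 4.19, SE 0.62, adjusted p = 0.00509) and Cxcl10 (66.5 ± 20.8 to 848 ± 557; 3.51, SE 0.57, adjusted p = 0.008). Tnf rose by 1.62 (adjusted p = 0.00995), Il6 by 2.09 (adjusted p = 0.0338) and Nos2, the inducible nitric oxide synthase, by 1.93 (adjusted p = 0.0371). The receptor gene Tlr2 rose from 602 ± 22.6 to 1848 ± 203 (adjusted p = 0.0165) and its adaptor Myd88 from 276 ± 45.6 to 839 ± 110 (adjusted p = 0.0163). Siglece, a sialic acid receptor, rose from 129 ± 52.4 to 456 ± 188 (1.81, adjusted p = 0.0215). Ctsd, which encodes a lysosomal protease, fell from 6287 ± 384.5 to 1863 ± 248 (-1.76, SE 0.27, adjusted p = 0.00663). Apoe, the apolipoprotein gene activated by LXR, fell from 212 ± 67.6 to 37.6 ± 1.43 (-2.43, SE 0.52, adjusted p = 0.0241). The LXR target Arl4c also fell (1934 ± 409 to 781 ± 118; adjusted p = 0.022), and so did Pparg, a nuclear receptor gene (2987 ± 343 to 1320 ± 159; adjusted p = 0.0241). The cholesterol exporters Abca1 (-0.26, adjusted p = 0.665) and Abcg1 (0.35, adjusted p = 0.865) and the desaturase gene Scd2 (-0.64, adjusted p = 0.368) did not pass the test. Socs3, Nfkbie, Il1b, Edn1, Cd40 and Ctsd kept adjusted p under 0.05 without any 1 of the 4 libraries compared. Il6, Nos2, Apoe, Arl4c, Pparg, Myd88 and Tlr2 lost it without any 1 of them (LPS replicates 1 and 2, PBS replicates 1 and 2; adjusted p = 0.0503 to 0.249). Tnf lost it without LPS replicate 1 (0.0623), LPS replicate 2 (0.0638) or PBS replicate 2 (0.0926). Ccl5 lost it without LPS replicate 1 (0.0527) or PBS replicate 2 (0.06), and Cxcl10 without LPS replicate 1 (0.0667) or PBS replicate 1 (0.0535). Siglece lost it without LPS replicate 2 (0.133) or PBS replicate 1 (0.125).

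As groups, all 35 NF-kB inflammatory genes lay above 0 at 2 h, with a median log2 change of 1.34 relative to all genes. Of these, 13 rose among all genes tested and 23 adjusted over the list alone (camera adjusted p = 3.49e-16; adjusted p = 0.00632 with an estimated correlation). All 31 measured interferon response genes also lay above 0 (median 2.15), and 13 rose among all genes and 27 adjusted over the list alone (camera adjusted p = 2.31e-17; adjusted p = 0.284 with an estimated correlation). Of 20 TLR4 signalling genes, 16 lay above 0 (median 0.29), and 4 rose, or 5 adjusted over the list alone (adjusted p = 0.0162; 0.47 as adjusted p with an estimated correlation). The call for this list was lost without LPS replicate 2 (0.384, adjusted p = 0.0906) or PBS replicate 1 (0.152, adjusted p = 0.27), and its median was 0.451 without LPS replicate 1 and 0.436 without PBS replicate 2. Among 17 measured LXR targets, 11 lay below 0 (median -0.55), and 3 fell, among them Apoe and Arl4c, also 3 adjusted over the list alone (adjusted p = 0.0162; adjusted p = 0.144 with an estimated correlation). This list call ended without LPS replicate 2 (-0.21, adjusted p = 0.105) or PBS replicate 1 (-0.304, adjusted p = 0.0745), and the median was -0.357 without PBS replicate 2. Of 20 macrophage identity genes, 15 lay below 0 (median -0.35), and 1 fell, both among all genes and adjusted over the list alone (adjusted p = 0.0162; adjusted p = 0.434 with an estimated correlation). That call was lost without LPS replicate 2 (-0.438, adjusted p = 0.0546) or PBS replicate 2 (-0.18, adjusted p = 0.395), and the median was -0.669 without PBS replicate 1. The anti-inflammatory list had 2 members that rose and 1 that fell (3 and 1 adjusted over the list alone), with a median of -0.145 but a mean of 0.151 (adjusted p = 0.947). The Siglec list had 2 that rose, Siglece and Siglecg (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.763). Cholesterol synthesis genes (0.763), fatty acid synthesis genes (0.151) and housekeeping genes (0.755) gave no list call, and none of their members passed among all genes. Fatty acid synthesis genes passed as a list without PBS replicate 2 (-0.357, adjusted p = 0.025).

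**Figure D2:**
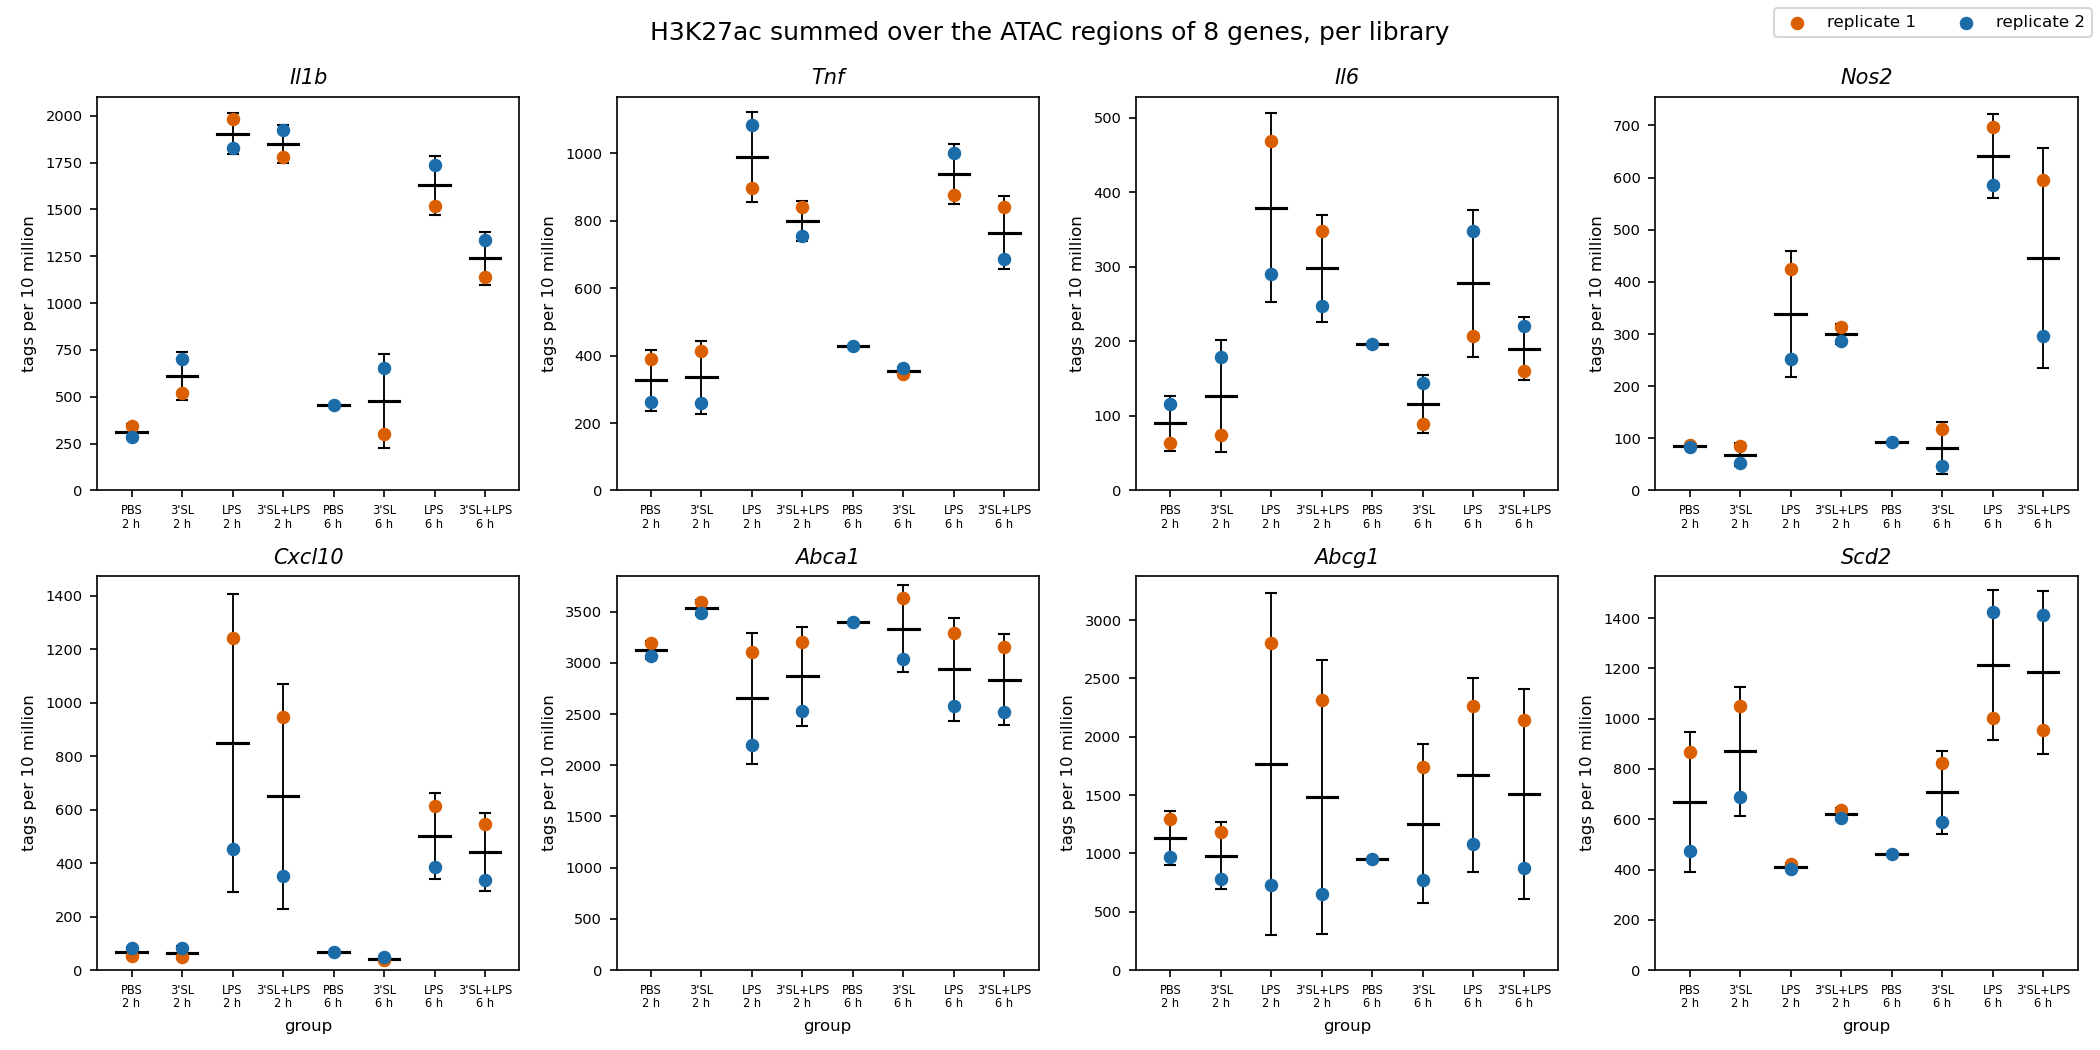
H3K27ac summed over the ATAC regions of 8 genes in each library, in tags per 10 M (y axes), by group (x axes), where points are libraries, bars means and whiskers SD. Il1b lies at 314 ± 38.9 with PBS and 1904 ± 108 with LPS at 2 h, and at 1851 ± 102 with 3'SL and LPS.

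At single regions, H3K27ac at 2 h of LPS was higher at 2380 and lower at 1600 of 77387 ATAC regions. Tnfaip3 restrains NF-kB, and an intergenic region at -62958 bp from its start (chromosome 10, 19077868 to 19078868, mm10) rose from 5.08 ± 7.19 to 240.3 ± 54.7 normalised tags (log2 change 6.16, SE 1.15, adjusted p = 0.0129). A region in intron 6 of 24 of Nfkb1, which encodes an NF-kB subunit (chromosome 3, 135639753 to 135640753), rose 190-fold over a single vehicle tag (counting interval 33.7 to 7520; adjusted p = 0.00296). A region in intron 7 of 13 of Slco2b1, an organic anion transporter gene (chromosome 7, 99674514 to 99675514), fell from 367 ± 167 to 25.8 ± 8.76 (-3.74, SE 0.47, adjusted p = 0.00296). The regions at Nfkb1 and Slco2b1 kept adjusted p under 0.05 without any 1 library. Tnfaip3 lost it without LPS replicate 1 (0.0926), LPS replicate 2 (0.0649) or PBS replicate 2 (0.107). The total of 3980 became 867 without LPS replicate 1, 1024 without LPS replicate 2, 1742 without PBS replicate 1 and 502 without PBS replicate 2. With the replicate as a block it was 17807 (9119 higher, 8688 lower). By edgeR it was 3499, by edgeR with the block 17809 and by DESeq2 7157. Scaling by library totals over the regions used moved the split from 2380 higher and 1600 lower to 2155 and 2195.

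At 6 h, 3 of the named genes passed the test against the lone PBS library. Edn1 rose from 551 to 2617 ± 208 normalised tags (SD, n = 2; log2 change 2.24, SE 0.25, adjusted p = 0.00883), Socs3 from 512 to 3487 ± 757 (2.75, SE 0.34, adjusted p = 0.0102) and Ccl5 from 101 to 2085 ± 563 (4.33, SE 0.76, adjusted p = 0.0345). With the replicate as a block, limma also called Il1b (1.84, adjusted p = 0.0772 without and 0.00358 with the block), Nos2 (2.77, 0.0649 and 0.00156), Cxcl10 (2.87, 0.112 and 0.0185), Tnf (1.13, 0.198 and 0.0426) and, lower, Arl4c (-1.70, 0.0552 and 0.00437). Il6 (0.45, adjusted p = 0.842), Abca1 (-0.22, 0.848), Abcg1 (0.71, 0.838) and Scd2 (1.37, 0.213) passed in neither. Edn1 lost its call without LPS replicate 2 (0.0803), as did Socs3 (0.0924), and Ccl5 lost it without LPS replicate 1 (0.148) or LPS replicate 2 (0.165). Of the NF-kB genes 30 of 35 lay above 0 (median 0.98), and 1 rose, or 12 adjusted over the list alone (adjusted p = 1.49e-10; 0.0235 as adjusted p with an estimated correlation, which became 0.0519 with the block). Of the interferon genes 30 of 31 lay above 0 (median 1.43), and 1 rose, or 12 adjusted over the list alone (adjusted p = 1.36e-12; adjusted p = 0.686 with an estimated correlation). Cholesterol synthesis genes lay above 0 in 20 of 25 cases (median 0.92), and the list passed (adjusted p = 0.000164; adjusted p = 0.686 with an estimated correlation) although 0 single members did by limma, 0 adjusted over the list alone. TLR4 signalling genes were called as a list with the block alone (median 0.37, adjusted p = 0.0293, against 0.212 without). The LXR target list had a median of 0.448 but a mean of -0.038 (adjusted p = 0.769). The macrophage identity list passed only without LPS replicate 2 (-0.457, adjusted p = 0.029, against 0.0807 with all libraries).

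Across regions at 6 h of LPS, H3K27ac was higher at 421 and lower at 102. The promoter region 71 bp from the start of Acod1, which makes the metabolite itaconate (chromosome 14, 103046583 to 103047583), held 576 ± 184 normalised tags with LPS and 0 in PBS, at least 230-fold higher from pooled tags over a floor of 3 (adjusted p = 0.0272). A region in the 5' UTR, exon 1 of 8, of St6gal1, which encodes a sialyltransferase (chromosome 16, 23224360 to 23225360), fell from 92.6 to 3.87 ± 3.62 (-4.50, SE 0.69, adjusted p = 0.0213). Without LPS replicate 1 and without LPS replicate 2, adjusted p became 0.113 and 0.153 for Acod1. St6gal1 lost its call only without LPS replicate 2 (0.119). The total of 523 became 12 without LPS replicate 1 and 0 without LPS replicate 2, and it was 7105 with the block (3926 higher, 3179 lower). By edgeR it was 96, by edgeR with the block 6403, by DESeq2 2339, and 10102 regions had an unadjusted p under 0.05 in limma. Tests by edgeR and DESeq2 were not run without single libraries.

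Binding of p300 after 2 h of LPS rose at genes of the same kind. Cxcl10 went from 8.45 normalised tags in the lone PBS library to 569 ± 255 (SD, n = 2; log2 change 5.84, SE 0.66, adjusted p = 0.00135). Il1a, which encodes IL-1α, rose from 84.5 to 1133 ± 393 (3.68, SE 0.43, adjusted p = 0.00151). Socs3 rose from 253.5 to 3053 ± 939 (3.55, SE 0.42, adjusted p = 0.00159) and the chemokine gene Ccl4 from 177.5 to 1324 ± 81.0 (2.89, adjusted p = 0.00184). Nos2 (3.43, adjusted p = 0.015) and Il10, an anti-inflammatory cytokine gene (148 to 595 ± 71.9; 2.00, adjusted p = 0.0261), also rose. Il1b (1.94, adjusted p = 0.0925), Tnf (1.65, 0.248) and Il6 (0.89, 0.427) passed only with the replicate as a block (0.00115, 0.0306 and 0.0335). Abca1 (0.21, 0.912), Abcg1 (0.31, 0.917) and Scd2 (0.06, 0.984) passed in neither. Of the 35 NF-kB genes all lay above 0 (median 1.69), and 8 rose, or 26 adjusted over the list alone (adjusted p = 1.66e-21; 0.000392 as adjusted p with an estimated correlation). Of 31 interferon genes 30 lay above 0 (median 1.56), and 7 rose, or 16 adjusted over the list alone (adjusted p = 3.27e-15; adjusted p = 0.218 with an estimated correlation). Of 19 TLR4 signalling genes 16 lay above 0 (median 0.51), and 1 rose, or 2 adjusted over the list alone (adjusted p = 0.0247; adjusted p = 0.218 with an estimated correlation). This call was lost without LPS replicate 2 (0.5, adjusted p = 0.0548). The anti-inflammatory list had 3 that rose, also 3 adjusted over the list alone, and no list call (adjusted p = 0.649). Without LPS replicate 1, LXR targets (-0.565) and macrophage identity genes (-0.525) were called lower, with adjusted p = 0.0389 each. Cxcl10, Il1a, Socs3 and Ccl4 kept their calls without either LPS library, but Nos2 and Il10 lost theirs without LPS replicate 1 (0.109 and 0.0998) and LPS replicate 2 (0.0574 and 0.124). On the authors' scaling, which moved the median of all regions by -0.679 at 2 h and -0.955 at 6 h, none of these genes passed (adjusted p = 0.999), so changes are given relative to the TMM scale. The shift on that scaling was -0.575 and -0.668 for 3'SL against PBS and 0.32 for 3'SL with LPS against LPS at 6 h.

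Of 62225 regions tested, 1350 were higher and 97 lower in p300 at 2 h of LPS. A region at -8627 bp from the start of Socs3 (chromosome 11, 117977893 to 117978093) held 720 ± 333 normalised tags against 0 in PBS, at least 115-fold higher (adjusted p = 0.000173). One near Ccl5 (chromosome 11, 83534901 to 83535101) held 331 ± 125 against 0, at least 52.7-fold higher (adjusted p = 0.0003). Of the 1350 higher regions, 709 (52.5%) had 0 tags in the lone PBS library, against 11.5% of all regions tested. The total of 1447 was 330 without LPS replicate 1, 505 without LPS replicate 2 and 4406 with the block (3507 higher, 899 lower). By edgeR it was 79, by edgeR with the block 2749, by DESeq2 319, and 1 with limma on the authors' scaling. At 6 h, 249 regions were higher and 14 lower. The total of 263 became 9 without LPS replicate 1, 5 without LPS replicate 2 and 1510 with the block. By edgeR it was 0, by edgeR with the block 1868, by DESeq2 254, and 0 on the authors' scaling, with 6001 at an unadjusted p under 0.05 in limma. Il1a alone of the named genes passed at 6 h (77.8 to 486 ± 15.0; log2 change 2.63, SE 0.43, adjusted p = 0.0315), and not without LPS replicate 1 (0.174) or LPS replicate 2 (0.208). With the block Nos2 (3.13, adjusted p = 0.000103), Cxcl10 (3.12, 0.00175), Socs3 (2.19, 0.000309) and Il6 (1.22, 0.0153) passed too. A region in intron 2 of 7 of St6gal1 (chromosome 16, 23280522 to 23280722) fell at 6 h from 279 to 22.6 ± 8.98 (-3.62, SE 0.74, adjusted p = 0.0432). It was lost without LPS replicate 1 (0.115) and LPS replicate 2 (0.198). NF-kB genes lay above 0 in 33 of 35 cases at 6 h (median 1.07; 1 rose, or 6 adjusted over the list alone; adjusted p = 1.32e-12; adjusted p = 0.00187 with an estimated correlation). Interferon genes did so in 30 of 31 (median 1.33; 0 rose by limma, or 12 adjusted over the list alone; adjusted p = 3.34e-12; adjusted p = 0.44 with an estimated correlation), and their median was 0.785 without LPS replicate 1. Without LPS replicate 2, cholesterol synthesis genes were called higher (0.892) and housekeeping genes lower (-0.475) at 6 h, with adjusted p = 0.024 each.

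The marks moved together under LPS. Across 59602 regions tested for both, Spearman's rho between the log2 changes of H3K27ac and p300 was 0.504 at 2 h and 0.510 at 6 h; regions are not independent replicates. Signs were shared at 66.6% and 68.1%. Of the H3K27ac calls also tested for p300, 3480 of 3768 (92.4%) had the same sign in p300 at 2 h and 485 of 501 (96.8%) at 6 h. Consensus NF-kB sites lay in 15.4% of regions with higher H3K27ac at 2 h against 3.67% of matched regions (odds ratio 4.78, adjusted p = 1.17e-86 by Fisher's exact test over 56 tests), and in 21.6% of regions with higher p300 against 3.63% (odds ratio 7.30, adjusted p = 1.78e-94). ISRE sites, bound by interferon regulatory factors, lay in 9.45% of regions with higher H3K27ac at 2 h against 3.54% (adjusted p = 2.4e-29). Regions with lower H3K27ac at 2 h held fewer NF-kB sites (1.75% against 4.46%, adjusted p = 5.26e-07) and more AP-1 sites (20.9% against 16.4%, adjusted p = 0.000177) and PU.1 sites (13% against 10.6%, adjusted p = 0.0247). AP-1 sites were also more frequent in regions with higher p300 at 2 h (21.6% against 18.4%, adjusted p = 0.0346), and at 6 h the share in regions with lower H3K27ac was 10.8% against 15.9% (adjusted p = 0.453).

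Adding 3'SL to LPS gave no H3K27ac call at single genes in limma, with or without the block. At 6 h the levels were, with 3'SL and LPS against LPS alone, 1238 ± 143 and 1628 ± 155 normalised tags for Il1b (SD, n = 2 each; log2 change -0.40, SE 0.33), 764 ± 108 and 938 ± 88.6 for Tnf (-0.30, SE 0.28). They were 190.2 ± 42.2 and 278 ± 98.8 for Il6 (-0.51) and 445 ± 211 and 641 ± 79.7 for Nos2 (-0.60). Each had an adjusted p of 1 in limma, though these 4 genes, Cxcl10, Abca1, Abcg1 and Scd2 all lay lower within both replicate numbers. The same adjusted p held for Edn1 (1617 ± 8.50 and 2617 ± 208; -0.69, SE 0.20), Siglece (296 ± 42.9 and 496 ± 64.4; -0.74), Irak3, an inhibitor of TLR signalling (1301 ± 133 and 2185 ± 459.6; -0.73), Cxcl10 (-0.18), Abca1 (-0.05), Abcg1 (-0.19) and Scd2 (-0.04). At 2 h, Il1b (-0.04), Tnf (-0.31), Il6 (-0.33), Nos2 (-0.12), Cxcl10 (-0.38), Abca1 (0.12), Abcg1 (-0.22) and Scd2 (0.59; 621 ± 23.3 and 411 ± 14.7) likewise had an adjusted p of 1. So did Oasl1, an interferon-stimulated gene (395 ± 43.4 and 614 ± 17.2; -0.64).

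Some lists were called in H3K27ac at the preset correlation. At 6 h the NF-kB list was lower with 3'SL, with 28 of 35 genes below 0 and a median of -0.28 relative to all genes (adjusted p = 3.65e-10; adjusted p = 0.0241 with an estimated correlation, and 0.0724 when the replicate was a block as well). This call was lost without LPS replicate 2 (-0.164), and the median was -0.45 without LPS replicate 1. At 2 h, 26 of 35 lay below 0 (median -0.12, adjusted p = 0.0252; adjusted p = 0.42 with an estimated correlation). This was lost without any 1 of the libraries (medians -0.132 to -0.03). The interferon list at 2 h had 29 of 31 genes below 0 (median -0.38, adjusted p = 5.86e-07; adjusted p = 0.723 with an estimated correlation). Its median turned to 0.242 without 3'SL with LPS replicate 2 and to 0.261 without LPS replicate 1. It was -1.02 without 3'SL with LPS replicate 1 and -0.926 without LPS replicate 2. In this comparison, fits without 1 library had no block and set unequal mixes of replicate numbers against each other. Such turns thus decide nothing. The fatty acid synthesis list was higher at 2 h, with 13 of 17 above 0 (median 0.18, adjusted p = 0.00649; adjusted p = 0.301 with an estimated correlation). It was lost without 3'SL with LPS replicate 1 (0.155) or LPS replicate 1 (0.118). The median was 0.276 without 3'SL with LPS replicate 2. No call was made for TLR4 signalling (adjusted p = 0.791 at 2 h, 0.155 at 6 h), LXR targets (0.219, 0.846), cholesterol synthesis (0.236, 0.742), macrophage identity (0.451, 0.313), anti-inflammatory genes (0.585, 0.944), housekeeping genes (0.668, 0.66), Siglecs (0.627, 0.104), or at 6 h for interferon (0.155) and fatty acid synthesis (0.173). Siglecs at 6 h passed with the block (-0.156, adjusted p = 0.0268; 0.148 with an estimated correlation), in regions of the H3K27ac peaks (-0.184, adjusted p = 0.0178) and within 10 kb (-0.145, adjusted p = 0.00879). The interferon list at 6 h passed without 3'SL with LPS replicate 1 (-0.322, adjusted p = 0.00379) or LPS replicate 2 (-0.359, adjusted p = 0.00686) and was 0.136 without LPS replicate 1. Cholesterol synthesis at 2 h passed without 3'SL with LPS replicate 2 (0.256, adjusted p = 0.00119). In no list did a member pass, among all genes or adjusted over the list alone; with the block, 2 NF-kB genes at 6 h were lower adjusted over the list alone.

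No region passed in H3K27ac for 3'SL with LPS against LPS alone by limma, edgeR or DESeq2, with or without the block where it was run. An unadjusted p under 0.05 in limma was reached by 244 regions at 2 h and 478 at 6 h of 77387. Regions of smallest p at 6 h included one in intron 10 of 16 of Cd163, a scavenger receptor gene (chromosome 6, 124319224 to 124320224; 6.70 ± 0.80 against 25.5 ± 8.30; log2 change -1.75, SE 0.48, adjusted p of 1). In simulated data, 50 regions per fold size, a 2-fold change was called in 2% of regions at 2 h and 0% at 6 h. A 4-fold change was called in 6% and 18%, an 8-fold one in 70% and 50% and a 16-fold one in 86% and 74%. Limma without the block thus rarely called changes of 4-fold or less.

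For p300, 3'SL with LPS against LPS alone called no region at 2 h or 6 h by limma, edgeR or DESeq2. Unadjusted p under 0.05 in limma was found at 698 and 1856 of 62225 regions (1699 and 3885 with the block, smallest adjusted p = 0.549 and 0.744). The levels at 2 h were 860 ± 41.8 and 1324 ± 81.0 normalised tags for Ccl4 (SD, n = 2 each; -0.62) and 306 ± 2.06 and 197 ± 3.67 for Arl4c (0.64), with an adjusted p of 1 in limma. With the same adjusted p, changes at 2 h and 6 h were 0.23 and -0.17 for Il1b, -0.65 and 0.05 for Tnf, -0.05 and -0.48 for Il6, and -0.40 and -0.17 for Nos2. They were -0.14 and -0.33 for Cxcl10, 0.14 and 0.31 for Abca1, -0.13 and 0.13 for Abcg1, and 0.20 and 0.33 for Scd2. LXR targets at 6 h were higher as a list, with 14 of 17 above 0 (median 0.34, adjusted p = 0.0292; adjusted p = 0.416 with an estimated correlation). It was lost without 3'SL with LPS replicate 1 (0.347, adjusted p = 0.213), LPS replicate 1 (0.449, adjusted p = 0.104) or LPS replicate 2 (0.344, adjusted p = 0.096). It was also lost in regions of the transcription factor peaks (0.145, adjusted p = 0.447), within 10 kb (0.204, adjusted p = 0.401), with RLE factors (0.334, adjusted p = 0.0508) and on the authors' scaling (0.355, adjusted p = 0.198). With the block, 3 lists at 2 h passed that otherwise did not (adjusted p = 0.0972 each): anti-inflammatory genes higher (median 0.23, adjusted p = 0.0205), and NF-kB (-0.08, adjusted p = 0.0339) and interferon genes (-0.20, adjusted p = 0.0339) lower. With an estimated correlation and the block, adjusted p was 0.331, 0.331 and 0.647. The interferon list at 2 h passed without 3'SL with LPS replicate 1 (-0.804, adjusted p = 3.2e-07) or LPS replicate 2 (-0.59, adjusted p = 7.27e-07), and was 0.299 without LPS replicate 1 and 0.266 without 3'SL with LPS replicate 2. A simulated 8-fold change was called in 36% of regions at 2 h and 42% at 6 h, a 16-fold change in 74% and 80%, a 4-fold change in 10% and 6%, and a 2-fold change in 0% and 0%.

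Regions that LPS changed in the other mark were then followed as classes in 3'SL with LPS against LPS alone. H3K27ac was lower at 94.4% of the 249 regions where LPS raised p300 at 6 h, with a median log2 change of -0.56 relative to all regions (camera adjusted p = 1.86e-28; adjusted p = 0.198 with an estimated correlation). With the block the class held 1234 regions and the median was -0.42 (adjusted p = 1.06e-24; adjusted p = 0.0623 with an estimated correlation). The median was -0.247 within replicate 1 and -0.892 within replicate 2. It was -0.886 without 3'SL with LPS replicate 1 and -0.222 without 3'SL with LPS replicate 2. At 2 h the 1350 induced regions had a median of -0.16, with 70.4% below 0 (adjusted p = 5.15e-05; adjusted p = 0.386 with an estimated correlation). That call was lost without 3'SL with LPS replicate 2 (-0.002) or LPS replicate 1 (-0.022). The median was -0.33 without 3'SL with LPS replicate 1 and -0.292 without LPS replicate 2. Regions repressed by LPS lay higher, by 0.17 at 2 h (97 regions, adjusted p = 0.00104) and 0.18 at 6 h (495 regions of smallest p, since 14 were called lower in p300; adjusted p = 2.25e-05), each with adjusted p = 0.386 with an estimated correlation. With the block these medians were 0.0663 (895 regions) and 0.177 (275 regions), and that of the induced class at 2 h was -0.113 (3497 regions). At 2 h the repressed call was lost without 3'SL with LPS replicate 1 (0.17, adjusted p = 0.0623), LPS replicate 1 (0.074, adjusted p = 0.0649) and on the authors' scaling (0.044, adjusted p = 0.48), with 0.099 without 3'SL with LPS replicate 2. At 6 h it turned to -0.095 without 3'SL with LPS replicate 2 and was lost without LPS replicate 1 (0.035). It was 0.385 without 3'SL with LPS replicate 1 and 0.309 without LPS replicate 2. In p300, induced regions were lower by a median of -0.12 at 2 h (2220 regions, adjusted p = 0.035) and -0.29 at 6 h (408 regions, adjusted p = 0.000169), and repressed regions higher by 0.21 at 6 h (93 regions, adjusted p = 0.035), each with adjusted p = 0.386 with an estimated correlation. With the block these medians were -0.107 (6636 regions), -0.181 (3560 regions) and 0.213 (2746 regions). At 2 h the induced call was lost without 3'SL with LPS replicate 1 (-0.193, adjusted p = 0.104), its replicate 2 (-0.109, adjusted p = 0.186) or LPS replicate 1 (-0.039, adjusted p = 0.374). At 6 h it was lost without 3'SL with LPS replicate 2 (-0.058, adjusted p = 0.362), with -0.53 without 3'SL with LPS replicate 1 and -0.183 without LPS replicate 1. The repressed class at 6 h was lost without 3'SL with LPS replicate 1 (0.252, adjusted p = 0.123) or 2 (0.212, adjusted p = 0.108), turned to -0.018 (adjusted p = 0.603) without LPS replicate 2 and was 0.363 without LPS replicate 1. The repressed p300 class at 2 h (1505 regions, median 0.12, adjusted p = 0.08) passed with the block (0.114, adjusted p = 0.0492; 0.254 with an estimated correlation). It also passed without 3'SL with LPS replicate 2 (0.237, adjusted p = 0.00189) or LPS replicate 1 (0.329, adjusted p = 0.000129), but was -0.09 without LPS replicate 2 and -0.021 without 3'SL with LPS replicate 1.

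**Figure D3:**
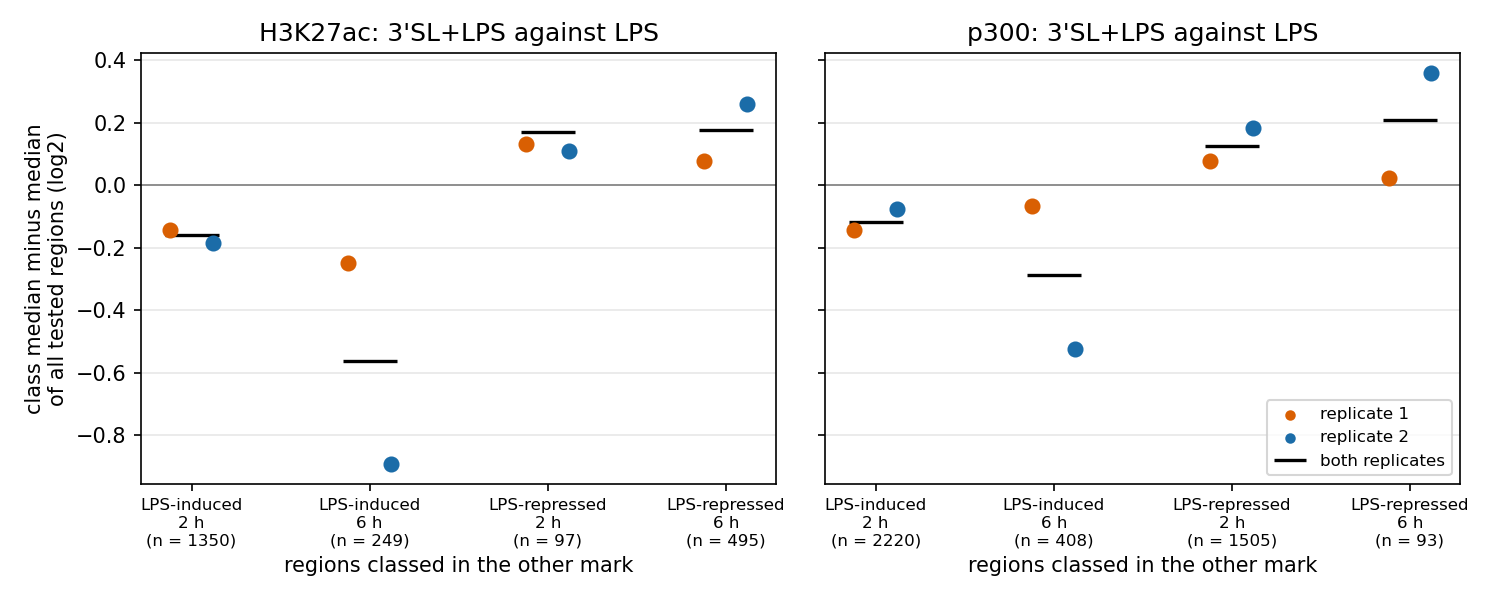
Median log2 change of each LPS-induced or LPS-repressed class minus the median of all tested regions (axis in log2 units), 3'SL with LPS against LPS, where points are the values within each replicate and lines the value over both. For H3K27ac at 6 h the induced class lies at -0.56, with -0.247 in replicate 1 and -0.892 in replicate 2.

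Without LPS, 3'SL changed H3K27ac at no region by limma, edgeR or DESeq2 (unadjusted p under 0.05 in limma at 446 regions at 2 h and 1116 at 6 h). These comparisons use the same PBS libraries as LPS against PBS. Il1b at 2 h stood at 612 ± 126 normalised tags with 3'SL and 314 ± 38.9 with PBS (SD, n = 2 each; log2 change 0.95, adjusted p of 1). Srebf1, a regulator of lipid synthesis, stood at 6 h at 715 ± 29.2 against 474 in the lone PBS library (0.59). The sterol enzyme gene Hsd17b7 stood at 51.4 ± 9.83 against 21.4 (1.22) and the complement gene C1qa at 133.5 ± 39.9 against 211 (-0.69), each with an adjusted p of 1. The cholesterol synthesis list was higher at 2 h, with 23 of 25 genes above 0 (median 0.29, adjusted p = 0.000139; adjusted p = 0.978 with an estimated correlation). Its median turned to -0.151 without 3'SL replicate 1 and -0.203 without PBS replicate 2, and was 0.683 without 3'SL replicate 2 and 0.785 without PBS replicate 1. These fits too compared unequal mixes of replicate numbers without a block. At 6 h 17 of 25 lay above 0 (median 0.59, adjusted p = 0.00165; adjusted p = 0.538 with an estimated correlation), which was lost without 3'SL replicate 1 (0.245, adjusted p = 0.484). The macrophage identity list was lower at 6 h, with 19 of 20 genes below 0 (median -0.22, adjusted p = 0.00292; adjusted p = 0.538 with an estimated correlation). This was lost without 3'SL replicate 1 (-0.113, adjusted p = 0.484), with -0.342 without 3'SL replicate 2. With the block alone, interferon genes (-0.257, adjusted p = 0.0426; 0.213 without) and stromal or erythroid markers (-0.408, adjusted p = 0.0426; 0.485 without) were lower at 6 h. With an estimated correlation their adjusted p was 0.627 and 0.59. Lists called lower at 6 h without 3'SL replicate 2, but not with all libraries and no block, were NF-kB (-0.314), TLR4 signalling (-0.351) and interferon (-0.445). At 2 h, without PBS replicate 1, they were TLR4 signalling (-0.147, adjusted p = 0.0317), interferon (-0.364, adjusted p = 0.0317) and macrophage identity (-0.24, adjusted p = 0.00512). Interferon genes also passed at 2 h without 3'SL replicate 2 (-0.363, adjusted p = 0.000496). No member of any list passed, among all genes or adjusted over the list alone, by limma without the block.

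In p300, 3'SL for 2 h gave 6 of 15971 genes higher (37 with the block) and 9 regions higher and 0 lower. The regions included one in intron 2 of 14 of Evl, an actin regulator gene (chromosome 12, 108641081 to 108641281; 55.1 ± 8.30 normalised tags against 0 in the lone PBS library, at least 8.69-fold higher, adjusted p = 0.0435). All 9 had 0 tags in the PBS library. Without 3'SL replicate 1 and without 3'SL replicate 2 the count was 0. Adjusted p was then 0.328 and 0.237 for Evl. The count was 0 by edgeR, edgeR with the block, DESeq2 and limma on the authors' scaling, 58 with a pseudocount of 0.5, 0 with a pseudocount of 5 and 239 with the block (235 higher, 4 lower). Il1a stood at 227 ± 40.2 against 84.5 at 2 h (1.40, SE 0.43, adjusted p = 0.752) and 188 ± 4.11 against 77.8 at 6 h (1.26, adjusted p of 1). At 6 h no region passed (1354 at an unadjusted p under 0.05 in limma, 0 by edgeR and DESeq2, and 1 lower by edgeR with the block), and no list was called in p300 at either time with all libraries and the settings used throughout. Cholesterol synthesis at 6 h (median 0.33) passed with library totals (0.332, adjusted p = 0.0414), in regions of the factor peaks (0.484, adjusted p = 0.0333), within 10 kb (0.584, adjusted p = 0.0389) and without 3'SL replicate 2 (0.59, adjusted p = 0.00446). Anti-inflammatory genes at 2 h passed within 10 kb (0.314, adjusted p = 0.0265).

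The difference of differences, whether LPS acts otherwise with 3'SL present, was also tested per region, and so was the difference between 6 h and 2 h in the effect of 3'SL under LPS. By limma no region passed for the former in H3K27ac (231 at an unadjusted p under 0.05 at 2 h and 733 at 6 h) or p300 (2242 and 1262), except 10 lower regions in p300 at 2 h with the block. The change of the 3'SL effect from 2 h to 6 h had no call (257 in H3K27ac and 1007 in p300). By edgeR, edgeR with the block and DESeq2, 0 regions passed in any of these tests.

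Under the LXR agonist GW3965, the authors' lists held 24480 LXR peaks, 27651 SREBP peaks and 44251 p300 peaks. LXR and SREBP shared 12622 LXR peaks (51.6%), and 45.6% of SREBP peaks overlapped an LXR peak. An overlap with p300 was found for 74.4% of LXR and 76.6% of SREBP peaks, and with the ATAC regions for 84.1% and 73.6%. At Abca1, a cholesterol exporter gene, an LXR peak lay in the promoter (chromosome 4, 53159833 to 53160033, at -38 bp) and one shared by LXR, SREBP and p300 in intron 2 of 49 (53133589 to 53133789). At Abcg1 both factors had the same peak in intron 1 of 14 that overlapped p300 (chromosome 17, 31058830 to 31059030). The DR4 site of LXR occurred in 115 of 11834 peaks of LXR alone (0.972%) and 5 of 15025 of SREBP alone (0.0333%; odds ratio 29.5, p = 9.38e-35 by Fisher's exact test). The SRE site of SREBP occurred in 0.287% and 4.15% (odds ratio 0.0666, p = 3.77e-115 by Fisher's exact test). ATAC regions under LXR peaks were lower after LPS relative to all regions in H3K27ac at 2 h (median -0.18, adjusted p = 0.0424) and 6 h (-0.18, adjusted p = 0.039), and in p300 at 2 h (-0.23, adjusted p = 0.039) and 6 h (-0.20, adjusted p = 0.0366). Regions under SREBP peaks were lower at 2 h in H3K27ac (-0.20, adjusted p = 0.0471) and p300 (-0.23, adjusted p = 0.0471), and under p300 peaks in H3K27ac at 2 h (-0.20, adjusted p = 0.0424). Regions under none of these were higher in H3K27ac at 2 h (0.12, adjusted p = 0.0471). With an estimated correlation adjusted p was 0.232 for each H3K27ac class and 0.156 or 0.157 for p300. With the block no factor class passed (adjusted p = 0.0648 to 0.0826 for these). In H3K27ac at 2 h, leaving out 1 library ended the LXR call (LPS replicate 1: adjusted p = 0.0572, LPS replicate 2: 0.0742, PBS replicate 2: 0.25). It also ended the SREBP call (0.0572, 0.12 and 0.212), the call for none (0.0572, 0.112 and 0.266) and, for LPS replicate 2 and PBS replicate 2, the p300 call (0.12 and 0.195). At 6 h LXR was lost without LPS replicate 1 (0.167), with a median of -0.274 without LPS replicate 2. Regions under none passed at 6 h without LPS replicate 2 (0.156, adjusted p = 0.043). In p300, LXR was lost at 2 h without LPS replicate 2 (0.0742) and at 6 h without LPS replicate 1 (0.0577), and SREBP without LPS replicate 1 (0.0501) or 2 (0.12). With 3'SL alone at 6 h, H3K27ac was lower under LXR peaks (-0.09, adjusted p = 0.039; 0.194 with the block) and p300 peaks (-0.08, adjusted p = 0.0471; 0.0826 with the block), with adjusted p = 0.232 with an estimated correlation. With pooled vehicles the medians were 0.001 (adjusted p = 0.974) and -0.009 (adjusted p = 0.909). LXR was lost without 3'SL replicate 1 (-0.026, adjusted p = 0.689), with -0.205 without replicate 2, and p300 without either (0.147 and 0.135). At 2 h of 3'SL, regions under p300 peaks passed without PBS replicate 1 (-0.086, adjusted p = 0.0473). With 3'SL and LPS against LPS at 6 h, p300 was higher under LXR peaks (0.11, adjusted p = 0.0471; adjusted p = 0.157 with an estimated correlation and 0.0648 with the block). This was lost without 3'SL with LPS replicate 2 (0.019, adjusted p = 0.51) or LPS replicate 1 (0.088, adjusted p = 0.416).

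The p65 list of the other study held 41220 peaks, of which 329 lay past the ends of 6 mm10 chromosomes, by up to 6951397 bp on chromosome 7. Only 1144 of its peaks (2.78%) overlapped an ATAC region. The 40587 regions that came from p65 alone had a median H3K27ac of 0.755 deposited units with LPS at 2 h in replicate 2, against 61.1 at LXR regions. It was not compared further.

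**Figure D4:**
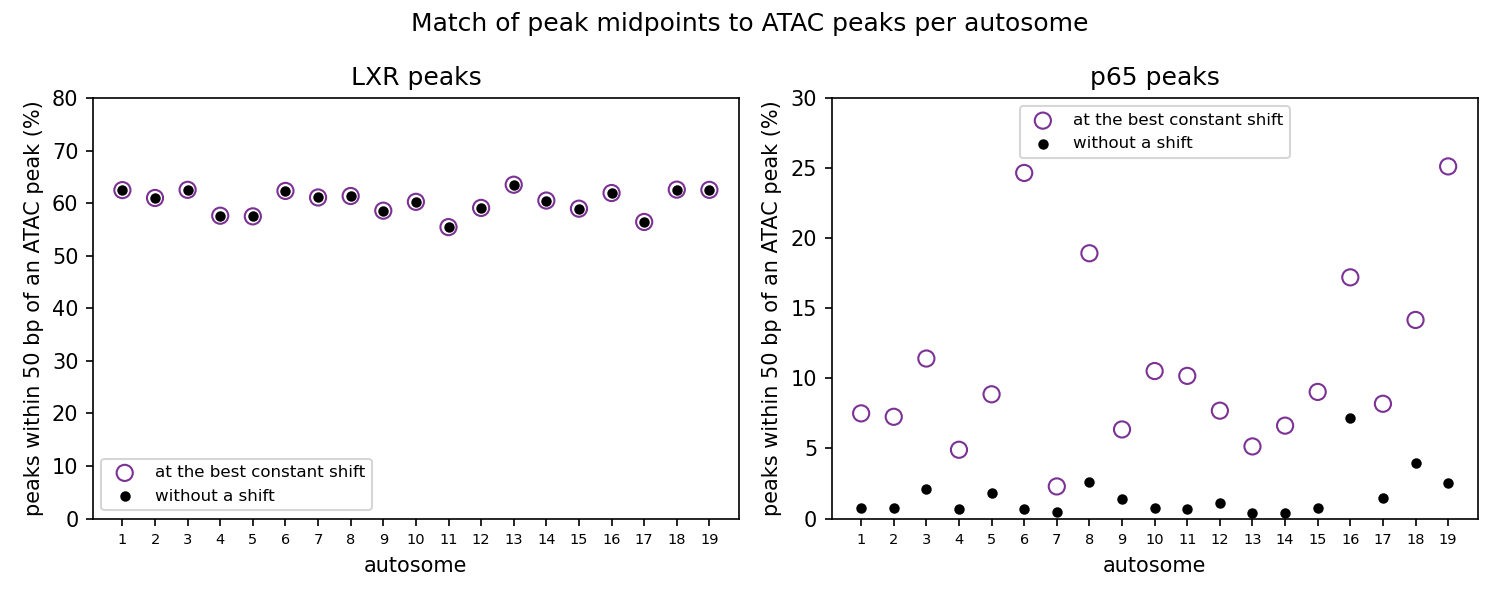
Peaks within 50 bp of an ATAC peak (%, y axis) on each autosome (x axis) for LXR and p65, with filled points for the deposited positions and open points for the best constant shift. LXR peaks match best unshifted on 19 of 19 autosomes, and p65 peaks match best at a shift beyond 100 bp on 18 and at -100 bp on chromosome 16.

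Markers of other cells gave no list call in limma without the block for any comparison of either mark with all libraries, TMM factors and the filter. In p300 under LPS at 6 h, neutrophil markers passed with library totals (0.476, adjusted p = 0.0359), without the filter (0.828, adjusted p = 0.0184) and on the authors' scaling (0.517, adjusted p = 0.0108). For 3'SL with LPS against LPS in H3K27ac, adjusted p at 2 h and 6 h was 0.668 and 0.313 for neutrophil, 0.585 and 0.782 for lymphoid, 0.585 and 0.313 for dendritic and 0.668 and 0.313 for stromal or erythroid markers. Members that rose with LPS at 2 h were Ccr7, a chemokine receptor gene of activated dendritic cells (2.63, adjusted p = 0.027) in H3K27ac, and Csf3r, the receptor for the neutrophil growth factor G-CSF (2.37, adjusted p = 0.0279), in p300. Ccr7 lost its call without LPS replicate 1 (0.0551), LPS replicate 2 (0.161), PBS replicate 1 (0.103) or PBS replicate 2 (0.141). Csf3r lost it without LPS replicate 1 (0.138) or 2 (0.0897). In H3K27ac, neutrophil markers passed without 3'SL replicate 2 for 3'SL against PBS at 2 h (0.688, adjusted p = 0.0363) and 6 h (1.22, adjusted p = 0.0152). They passed without 3'SL with LPS replicate 2 for 3'SL with LPS against LPS at 2 h (0.275, adjusted p = 0.0487) and without LPS replicate 2 for LPS at 6 h (1.59, adjusted p = 0.05). Stromal or erythroid markers passed for 3'SL with LPS against LPS at 6 h without 3'SL with LPS replicate 2 (0.889, adjusted p = 0.047) or LPS replicate 1 (0.915, adjusted p = 0.0239).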

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

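Tests chosen only after the result was seen were those of single replicates, of a lowered LPS response, of the replicate block on p300 calls and of H3K27ac at p300 calls with 0 vehicle tags.

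H3K27ac at LPS-induced regions moved further down with 3'SL under LPS at 6 h than at 2 h, by a median of -0.204 for the class of 2 h (adjusted p = 0.000198) and -0.31 for the class of 6 h (adjusted p = 6.54e-07), where the difference itself was tested. With an estimated correlation adjusted p was 0.804 for both. In p300 the medians were -0.0246 (adjusted p = 0.84) and -0.144 (adjusted p = 0.154), with no call. An H3K27ac vehicle library without a stated time, used only in pooled vehicles, held 16.2 M tags. Its share in the ATAC windows, 42.62% (8.65% to 8.85% in inputs), was the lowest of any H3K27ac library. In p300 at 2 h, the 3'SL effect differed with and without LPS at 10 regions with the replicate as a block and at 0 by limma without it.

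At 6 h, H3K27ac at the 249 LPS-induced regions lay lower with 3'SL and LPS than with LPS alone (median -0.56). Regions of matched mean level outside the LPS classes (median -0.0105) do not exclude weaker enrichment with 3'SL, since induced regions are higher under LPS. Replicate 1 (-0.247) argues against a single replicate as the whole source. Tags simulated without an effect (-0.00439) decide nothing, because the class came from p300 libraries they do not share. A lowering of the LPS response by 3'SL stays open as a hypothesis, since the adjusted p was 0.198 with an estimated correlation and the median ran from -0.886 to -0.222 without 1 of the 3'SL with LPS libraries. Weaker enrichment in replicate 1, or chance in the LPS libraries or in the cultures' response, cannot be told apart from it with n = 2.

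Many p300 regions were called higher than in vehicle at 2 h. The lone vehicle library, of 3.20 M tags, had 0 tags at 52.5% of those called with LPS and 72.3% with 3'SL and the block. This decides nothing, as calls were made against that library. Its depth as the whole source is argued against for LPS, where H3K27ac was higher at 92.4% of called regions with 0 vehicle tags and 65.9% of uncalled ones, but for 3'SL (58.2% and 48.1%) it cannot be told apart from a biological rise, as the marks shared their sign at only 54.3% of all regions. Replicate 1 set against a vehicle of replicate 2 is argued against as the whole source. The block kept 1447 of 1447 LPS calls (median change 4.49, and 4.37 with it). NF-kB sites in 21.6% of higher regions (3.63% of matched) argue against depth with LPS. A biological rise with LPS is left, and H3K27ac had the same sign at 1382 of 1447 (66.6% of all regions).

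Peaks of p65 rarely met open chromatin (2.78%). On 18 of 19 autosomes they met it best at a shift beyond 100 bp (at -100 bp on chromosome 16). LXR peaks did so unshifted on all 19. With 329 p65 peaks past mm10 chromosome ends, this argues against a p65 list on mm10. No biological explanation was tested.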

How the results depend on the processing

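Tests chosen after the data were seen were those by edgeR, with and without the block, and on the authors' scaling. Across all alternatives, 2020 gene list, 454 factor class and 86 LPS class medians kept their side of the threshold, including values never called, of either sign. Calls were lost in 31, 47 and 12, gained in 42, 10 and 4, and called values turned sign in 7, 1 and 2. Counts of regions that were 0 stayed 0 in 217 fits and rose in 2, and counts above 0 stayed within 1.5 times in 26 and moved further in 48. Of 40 gene calls, 4 were lost with RLE factors, 7 with library totals, 2 without the filter, 0 and 1 with pseudocounts of 0.5 and 5 and 25 on the authors' scaling. Without 1 library, 78 of 126 were lost. Of 208 uncalled values, 33 were gained with the block, 3 with library totals and 1 with RLE factors. Of 67 region calls, 1, 3, 4, 5, 8 and 39 were lost with RLE factors, library totals, no filter, pseudocounts of 0.5 and 5 and the authors' scaling, and 105 of 166 without 1 library. None of these turned sign, and the block ended none of them. Pooled vehicles, other region tables, DESeq2 and edgeR were not run for named regions and genes, nor pooled vehicles for gene lists. Lone vehicle libraries could not be left out, since no control would remain. Where leaving out a library left a group with 1, the lone sample was assumed to vary like the other groups. Depth limits p300, where 1 tag of the 2 h vehicle library is worth 3.13 units.

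With the replicate as a block, counts were 17807 for H3K27ac under LPS at 2 h, 7105 for H3K27ac under LPS at 6 h, 239 for p300 under 3'SL at 2 h, 4406 for p300 under LPS at 2 h, 1510 for p300 under LPS at 6 h and 10 for the difference of the 3'SL effect in p300 with and without LPS at 2 h. On the authors' scaling, counts were 2639 for H3K27ac under LPS at 2 h, 323 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h, 1 for p300 under LPS at 2 h and 0 for p300 under LPS at 6 h. With all vehicle libraries as 1 control (pooled vehicles), counts were 9452 for H3K27ac under LPS at 2 h, 5986 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h, 2620 for p300 under LPS at 2 h and 1363 for p300 under LPS at 6 h. With a pseudocount of 0.5, the count was 58 for p300 under 3'SL at 2 h. With a pseudocount of 5, counts were 0 for p300 under 3'SL at 2 h and 165 for p300 under LPS at 6 h. In regions of the factor peaks, counts were 2439 for H3K27ac under LPS at 2 h, 192 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h, 532 for p300 under LPS at 2 h and 55 for p300 under LPS at 6 h. By DESeq2, counts were 7157 for H3K27ac under LPS at 2 h, 2339 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h and 319 for p300 under LPS at 2 h. By edgeR, counts were 96 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h, 79 for p300 under LPS at 2 h and 0 for p300 under LPS at 6 h. By edgeR with the block, counts were 17809 for H3K27ac under LPS at 2 h, 6403 for H3K27ac under LPS at 6 h, 0 for p300 under 3'SL at 2 h, 1 for p300 under 3'SL at 6 h, 2749 for p300 under LPS at 2 h and 1868 for p300 under LPS at 6 h. With an overlap of at least 50% of the shorter peak, the shares of LXR peaks overlapping ATAC, SREBP and p300 were 77.2%, 47.9% and 71.4%. Those of SREBP peaks overlapping ATAC, LXR and p300 were 66.8%, 42.4% and 73.7%, and those of p300 peaks overlapping ATAC, LXR and SREBP 66.2%, 39.5% and 46.1%. With only the 50% of ATAC peaks of higher score they were 62.4%, 49.4% and 44.8% for LXR, SREBP and p300.

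Medians below are log2 values relative to all regions or genes, with 3'SL with LPS set against LPS and the others against PBS. With the replicate as a block, calls lost were H3K27ac under 3'SL at 6 h (LXR-bound -0.035 and p300-bound -0.067), H3K27ac under LPS at 2 h (LXR-bound -0.181, SREBP-bound -0.197, no-factor 0.12 and p300-bound -0.204) and H3K27ac under LPS at 6 h (LXR-bound -0.115). Also lost were p300 under 3'SL with LPS at 6 h (LXR-bound 0.109), p300 under LPS at 2 h (LXR-bound -0.183 and SREBP-bound -0.218) and p300 under LPS at 6 h (LXR-bound -0.149). With the replicate as a block, calls gained were H3K27ac under LPS at 6 h (TLR4 0.371), H3K27ac under 3'SL at 6 h (interferon -0.257 and stromal -0.408) and H3K27ac under 3'SL with LPS at 6 h (Siglec -0.156). Also gained were p300 under 3'SL with LPS at 2 h (LPS-repressed 0.114, NF-kB -0.078, anti-inflammatory 0.229 and interferon -0.2). On the authors' scaling, calls lost were H3K27ac under 3'SL with LPS at 2 h (LPS-repressed 0.044 and NF-kB -0.114), H3K27ac under 3'SL at 6 h (p300-bound -0.083) and p300 under 3'SL with LPS at 6 h (LXR targets 0.355). Also lost was p300 under LPS at 2 h (TLR4 0.468). On the authors' scaling, calls gained were p300 under LPS at 6 h (SREBP-bound -0.149, no-factor 0.165 and neutrophil 0.517), p300 under 3'SL with LPS at 6 h (no-factor -0.141) and p300 under LPS at 2 h (no-factor 0.284 and p300-bound -0.187). With pooled vehicles, the reversed value was H3K27ac under 3'SL at 6 h (LXR-bound 0.001). With pooled vehicles, calls lost were H3K27ac under LPS at 2 h (LXR-bound -0.176, SREBP-bound -0.194 and no-factor 0.12), H3K27ac under LPS at 6 h (LXR-bound -0.077) and H3K27ac under 3'SL at 6 h (p300-bound -0.009). Also lost was p300 under LPS at 2 h (SREBP-bound -0.197). With RLE factors, calls lost were p300 under 3'SL with LPS at 6 h (LXR-bound 0.106 and LXR targets 0.334). With library totals, calls lost were H3K27ac under 3'SL at 6 h (LXR-bound -0.085) and p300 under LPS at 2 h (TLR4 0.499). With library totals, calls gained were p300 under LPS at 2 h (no-factor 0.251), p300 under 3'SL at 6 h (cholesterol synthesis 0.332) and p300 under LPS at 6 h (neutrophil 0.476). Without the filter, calls lost were H3K27ac under LPS at 2 h (no-factor 0.082) and H3K27ac under 3'SL with LPS at 2 h (NF-kB -0.111). Without the filter, calls gained were H3K27ac under 3'SL at 6 h (no-factor 0.072) and p300 under LPS at 6 h (neutrophil 0.828). With a pseudocount of 0.5, calls lost were H3K27ac under LPS at 2 h (SREBP-bound -0.204 and no-factor 0.128), H3K27ac under 3'SL at 6 h (p300-bound -0.08) and p300 under 3'SL with LPS at 6 h (LXR-bound 0.112). Also lost was p300 under LPS at 2 h (SREBP-bound -0.226). With a pseudocount of 5, the call gained was H3K27ac under 3'SL at 6 h (no-factor 0.064). In regions of the factor peaks, calls lost were H3K27ac under 3'SL with LPS at 2 h (NF-kB -0.127) and p300 under 3'SL with LPS at 6 h (LXR targets 0.145). In regions of the factor peaks, the call gained was p300 under 3'SL at 6 h (cholesterol synthesis 0.484). In regions of the H3K27ac peaks, calls lost were H3K27ac under 3'SL with LPS at 2 h (fatty acid synthesis 0.074), H3K27ac under 3'SL at 6 h (macrophage identity -0.227) and H3K27ac under LPS at 2 h (macrophage identity -0.459). In regions of the H3K27ac peaks, calls gained were H3K27ac under 3'SL with LPS at 6 h (fatty acid synthesis 0.115 and Siglec -0.184). Within 10 kb of genes, the call lost was p300 under 3'SL with LPS at 6 h (LXR targets 0.204). Within 10 kb of genes, calls gained were H3K27ac under 3'SL with LPS at 6 h (Siglec -0.145), p300 under 3'SL at 2 h (anti-inflammatory 0.314) and p300 under LPS at 2 h (anti-inflammatory 0.383). Also gained was p300 under 3'SL at 6 h (cholesterol synthesis 0.584). With classes from the same mark, the call gained was p300 under 3'SL with LPS at 2 h (LPS-repressed 0.543), but tags simulated without a 3'SL effect gave 0.942 (0.826 to 1.05), since that class shares its LPS libraries with the comparison.

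Without 1 library, counts ran from 502 to 1742 for H3K27ac under LPS at 2 h, from 0 to 12 for H3K27ac under LPS at 6 h, at 0 for p300 under 3'SL at 2 h, from 330 to 505 for p300 under LPS at 2 h and from 5 to 9 for p300 under LPS at 6 h. Medians in H3K27ac under 3'SL with LPS at 2 h ran from -0.33 to -0.002 for LPS-induced, 0.074 to 0.17 for LPS-repressed, -0.132 to -0.03 for NF-kB, -0.252 to 0.256 for cholesterol synthesis, 0.118 to 0.276 for fatty acid synthesis, -1.024 to 0.261 for interferon and -0.633 to 0.298 for neutrophil. In H3K27ac under 3'SL with LPS at 6 h they ran from -0.095 to 0.385 for LPS-repressed, -0.45 to -0.164 for NF-kB, -0.359 to 0.136 for interferon and -0.26 to 0.915 for stromal. In H3K27ac under 3'SL at 6 h they ran from -0.205 to -0.026 for LXR-bound, -0.103 to -0.086 for p300-bound, -0.314 to -0.041 for NF-kB, -0.351 to 0.034 for TLR4, 0.245 to 0.865 for cholesterol synthesis, -0.445 to 0.036 for interferon, -0.342 to -0.113 for macrophage identity and -0.502 to 1.224 for neutrophil. In H3K27ac under LPS at 2 h they ran from -0.269 to -0.085 for LXR-bound, -0.255 to -0.125 for SREBP-bound, 0.069 to 0.179 for no-factor, -0.247 to -0.134 for p300-bound, -0.747 to -0.21 for LXR targets, 0.152 to 0.451 for TLR4, -0.385 to -0.079 for fatty acid synthesis and -0.669 to -0.18 for macrophage identity. In H3K27ac under LPS at 6 h they ran from -0.274 to -0.122 for LXR-bound, 0.033 to 0.156 for no-factor, -0.457 to -0.19 for macrophage identity and 0.142 to 1.589 for neutrophil. In H3K27ac under 3'SL at 2 h they ran from -0.086 to 0.028 for p300-bound, -0.147 to 0.157 for TLR4, -0.203 to 0.785 for cholesterol synthesis, -0.364 to 0.23 for interferon, -0.24 to 0.154 for macrophage identity and -0.822 to 0.712 for neutrophil. In p300 under 3'SL with LPS at 2 h they ran from -0.193 to -0.039 for LPS-induced, -0.09 to 0.329 for LPS-repressed, -0.447 to 0.248 for cholesterol synthesis and -0.804 to 0.299 for interferon. In p300 under 3'SL with LPS at 6 h they ran from -0.53 to -0.058 for LPS-induced, -0.018 to 0.363 for LPS-repressed, 0.019 to 0.163 for LXR-bound, 0.237 to 0.449 for LXR targets and -0.303 to 0.411 for interferon. In p300 under LPS at 2 h they ran from -0.226 to -0.213 for LXR-bound, -0.225 to -0.178 for SREBP-bound, -0.565 to 0.088 for LXR targets, 0.5 to 0.547 for TLR4 and -0.525 to 0.06 for macrophage identity. In p300 under LPS at 6 h they ran from -0.288 to -0.159 for LXR-bound, 0.046 to 0.892 for cholesterol synthesis and -0.475 to 0.03 for housekeeping. In p300 under 3'SL at 6 h they ran from 0.124 to 0.59 for cholesterol synthesis. With the block, genes called higher and lower went from 582 and 380 to 2158 and 1743 for H3K27ac under LPS at 2 h and from 67 and 28 to 658 and 650 at 6 h. For p300 they went from 246 and 26 to 1078 and 305 at 2 h and from 20 and 2 to 321 and 80 at 6 h. Genes higher went from 6 to 37 for p300 under 3'SL at 2 h and from 0 to 1 for H3K27ac under 3'SL at 6 h. For the difference of the 3'SL effect with and without LPS in p300 at 2 h, 5 genes were lower with the block and 0 without it. The cause of these changes was not tested.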

Other observations

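Sterol genes carried LXR and SREBP peaks in different arrangements. Srebf1 had an LXR peak in 1 promoter (chromosome 11, 60222412 to 60222612) and a peak of both in another (60210452 to 60210652). Mylip had an LXR peak in intron 2 of 6 (chromosome 13, 45391596 to 45391796) and an SREBP peak in its promoter (45389646 to 45389846). Insig1, which retains SREBP in the endoplasmic reticulum, had a peak of both in intron 1 of 4 (chromosome 5, 28071869 to 28072069) and an SREBP peak in its promoter (28071096 to 28071296). Within 100 kb, LXR and SREBP peaks numbered 11 and 6 at Abca1, 8 and 5 at Abcg1 and 4 and 7 at Insig1.

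The source names of the replicate 2 H3K27ac libraries of 3'SL with LPS read input. Their share in the ATAC windows was 73.2% to 76.7%, against 8.65% to 8.85% in inputs. The treatment label of the one at 2 h reads vehicle PBS, while Il1b stood there at 1923 normalised tags, against 286.7 in PBS and 1827 in LPS of replicate 2. Satellite regions took 8.93% to 14.3% of region tags in replicate 1 of p300 and 1.15% to 2.27% in replicate 2. Libraries of 1 replicate number and different groups correlated with a median r of 0.902 across H3K27ac regions, those of 1 group with different numbers with 0.892. For p300 these values were 0.621 and 0.642.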
